A study of Saccharomyces cerevisiae with 49 samples.

How the data were processed

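Gene expression was measured in synchronized budding yeast on 49 dual-colour oligonucleotide arrays, in 3 time courses. Per the labels, messenger RNA of synchronized cells carried Cy5 and messenger RNA of unarrested mid-log cells carried Cy3 on each array. The deposited values are log ratios, taken here as log2 of synchronized over mid-log cells. Their log base, centring and direction are not stated in the table. The direction follows the dyes named in the labels and was checked on AGA1, a mating adhesin gene, which was high at 0 min after alpha factor. Array medians lay between -0.071 and 0.021, and the lowest correlation between any 2 arrays was -0.295. The scanner, background correction, spot filter and normalization are not given in the sources used here.

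The table held 6258 probes, of which 5570 carried 1 gene symbol in the platform annotation and 688 carried none and were kept under their probe identity. The probes of 29 genes with several probes were averaged, which left 6228 features with 5540 named genes. Locus tags came from the RefSeq gene table and were used as identifiers for 5535 named genes. No genome coordinates were used. Arrays held between 4189 and 6110 values. For arrays only their number can be given as a limit on precision.

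Samples were grouped by course: 17 arrays of 1 alpha-factor culture, 16 arrays of cdc28 culture B and 16 arrays of cdc28 culture E. The letters B and E are the cultures of the labels. Strain, kind of arrest, temperature and culture are confounded between the alpha-factor and cdc28 courses. The release temperature of the cdc28 cultures differs between the series text and the sample labels, and is not used here. Each array was centred on its median before the fits.

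Periodic genes were called in each course alone with limma 3.58.1 in R 4.3.3. A cosine and a sine term, an intercept and a linear time trend were fitted to genes with values on at least 80% of the arrays of the course. Their joint F-test was adjusted by Benjamini-Hochberg, and a gene was called periodic at an adjusted p under 0.05. The period of a course was the value between 40 and 160 min, in steps of 1 min, with the highest median gain in R2 over the trend across the G1/S, histone and G2/M lists and a further list of M/G1 genes, whose own results are not reported here. Because the period was set on these lists, their high shares of periodic members are not independent of it. Period intervals are 95% intervals over 200 bootstraps of these marker genes. Amplitude is the distance from the fitted mean to the fitted peak on the log2 scale, and peaks are given within 1 period after release. Peak phases of genes periodic in both of a pair of courses were compared by their median absolute difference after removal of the mean offset, against 1000 random pairings of genes.

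Contrasts used the 15 arrays at the times that all courses share, 0, 30, 60, 90 and 120 min, and genes with values on at least 80% of them. limma fitted 1 mean for each of 10 groups of arrest and time, which left 5 residual degrees of freedom, all from the pairs of cdc28 cultures, and 4.21 prior degrees of freedom. The single alpha-factor array of each time is assumed to vary like the cdc28 pairs. Tests were two-sided with Benjamini-Hochberg adjustment over all genes of the contrast, and the threshold was an adjusted p under 0.05. The cdc28 changes against 0 min share the same 0 min arrays and are not independent of each other.

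The 18 gene lists covered a core set of cell cycle genes, G1/S targets of SBF and MBF, histones, S/G2 targets of Hcm1, the G2/M CLB2 cluster, and that list of M/G1 genes. They also covered M/G1 replication licensing genes with CLN3, SWI4 and FAR1 (the licensing list), pheromone response, heat shock chaperones, general stress, ribosome biogenesis, phosphate, sulfur, respiration, amino acid biosynthesis, alpha-cell markers, meiosis markers and ribosomal proteins. Members past the threshold were counted over all genes and with p adjusted over the list alone. Lists were tested for a shift with camera at a preset correlation of 0.01 and again with an estimated correlation, over 4469 features with values on all 15 arrays, in 7 contrasts. Membership among periodic genes was tested with the two-sided Fisher exact test, adjusted over the lists.

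The comparisons, tests, thresholds, gene lists, alternatives and the rule for named genes were chosen before the data were examined, except for 2 alternatives added afterwards, culture E fitted at the period of B and named genes only, and for 5 tests of explanations for patterns in the cdc28 cultures. For the periodic results that rule covered all members of the core list. It also covered the 10 genes outside every list with the largest median amplitude among genes periodic in all 3 courses. For the arrest difference at 0 min and the cdc28 change at 30 min it covered the 10 largest differences each way past the threshold and the 3 largest of each list. For the other contrasts it covered the 5 largest each way past the threshold. Some core genes and list members that the rule covered are not named below, and which were left out was not set by the rule.

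Alternatives were the values as deposited, quantile normalization, no filter or a complete filter on missing values, other time trends and periods, a minimum amplitude of 0.5, a minimum change of 1 on the log2 scale, and the median of probes. Further ones were the cdc28 cultures as blocks, the course or the slide as a random block, the letter in the array name as a covariate, a robust prior, an early window of arrays, and leaving out each array in turn. The fits were tested on simulated data with noise independent between arrays, and the periodic fits were given the true period. The shares below therefore leave out any correlation between arrays and any error in the period. Of 100 genes with an added amplitude of 1, the fits recovered 97%, 97% and 100% in the alpha-factor, B and E designs, with 5.91%, 7.1% and 7.49% false calls. At 0 min the arrest contrast recovered 3% of differences of 1 log2 unit and 55% of differences of 2, and the 30 min contrast recovered 24% and 72%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.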

Results

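Transcript levels were followed through the cell cycle of budding yeast on 49 arrays, as log2 ratios of synchronized over mid-log cells. The alpha-factor course came from 1 culture of a BY4741 strain that lacks BAR1, the protease that degrades the pheromone. Mating pheromone held these cells in G1, and 17 arrays covered the time up to 150 min after release. The cdc28 courses came from 2 cultures of cdc28-13 cells, which carry a temperature-sensitive allele of the cyclin-dependent kinase and were arrested at high temperature, then cooled. Culture B gave 16 arrays up to 225 min and culture E 16 arrays up to 160 min. Arrays held 4189 to 6110 values, and their number limits the precision. BAR1 had values on 0 alpha-factor arrays and on 32 cdc28 arrays.

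The first question was which transcripts oscillate after release from each arrest. In all 3 courses the mean peaks of the cell cycle lists came in the same sequence: G1/S genes, histones, S/G2 genes and then the G2/M cluster. The step from histones to S/G2 genes was smaller than the SD over S/G2 members, and the order of the lists was not tested. The period that described the marker genes best was 53 min after alpha factor (interval 52 to 56), 124 min in culture B (118 to 131) and 106 min in culture E (90 to 120). These courses covered 2.83, 1.81 and 1.51 cycles. The intervals are over genes of 1 culture and leave out variation between cultures. In culture E the median gain in R2 was 0.479 at 106 min and 0.452 at 124 min, so the 2 periods described it almost equally. Fitted at 124 min, culture E had 532 periodic genes. Whether the periods of B and E differ was not tested. Of 5359 genes tested after alpha factor, 1404 (26.2%) were periodic in limma, against 796 of 5598 (14.2%) in culture B and 328 of 5717 (5.74%) in culture E. An amplitude of at least 0.5 was reached by 482, 366 and 160 of them. These counts depended on the fit. With a period 10% longer they were 1211, 699 and 443. With a period 10% shorter they were 215, 488 and 211, without a time trend 1040, 548 and 95, with a quadratic trend 1493, 895 and 568, and with quantile normalization 1681, 1102 and 572. In culture E, 5 of 100 shuffles of the array order called as many genes as the real order, so an arbitrary order was not excluded for that count. Its count was 515 without the 0 min array, 196 without 40 min, 204 without 60 min, 202 without 70 min, 210 without 80 min and 568 without 160 min.

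G1/S genes, which SBF and MBF switch on at the start of the cycle, were periodic for 30 of 32 members after alpha factor, 29 of 31 in culture B and 19 of 32 in culture E. Adjusted over the list alone, 30, 29 and 29 passed. Their mean peak came at 13.0 ± 2.60 min (SD, n = 30 genes), 34.3 ± 7.21 min (n = 29) and 41.6 ± 5.94 min (n = 19). The G1 cyclin gene CLN2 (YPL256C) had amplitudes of 1.82 ± 0.28 (SE, 17 arrays), 1.73 ± 0.14 (15 arrays) and 1.17 ± 0.14 (16 arrays). CDC21, for thymidylate synthase, was periodic with amplitudes of 1.42, 1.30 and 0.80. RNR1 (YER070W), for the large subunit of ribonucleotide reductase, had an amplitude of 2.03 ± 0.23 after alpha factor and 1.66 ± 0.18 in culture B, and 1.09 ± 0.27 in culture E at an adjusted p of 0.0578. CLN1, CLB5 and CLB6 were periodic after alpha factor and in culture B, and had adjusted p of 0.121, 0.142 and 0.0779 in culture E. Whether these genes differ between courses was not tested. Membership of the list among periodic genes had Fisher exact adjusted p of 1.41e-14, 1.1e-21 and 2.48e-15.

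Histone genes followed, and all 9 were periodic in each course. They peaked at 23.0 ± 0.727 min after alpha factor, 53.1 ± 3.70 min in culture B and 61.3 ± 1.71 min in culture E (SD, n = 9 genes). HHF1, a histone H4 gene, had amplitudes of 1.71, 1.50 and 0.94, and HTA1, a histone H2A gene, had 1.37, 1.02 and 0.66. S/G2 targets of Hcm1 were periodic for 9 of 10, 9 of 10 and 6 of 10 members, with 9, 9 and 8 adjusted over the list alone. Their mean peaks came at 26.9 ± 7.73, 62.3 ± 12.1 and 68.1 ± 9.06 min (SD over periodic members). NDD1, for a co-activator of the G2/M cluster, had amplitudes of 0.56, 0.79 and 0.46. Fisher exact adjusted p were 1.71e-05, 8.23e-08 and 2.73e-11 for histones and 0.000112, 5.13e-07 and 1.77e-05 for the S/G2 list.

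The G2/M cluster peaked later, at 40.3 ± 3.99 min (SD, n = 18 genes), 93.1 ± 7.88 min (n = 17) and 91.3 ± 5.68 min (n = 15). It was periodic for 18 of 19, 17 of 19 and 15 of 18 members, and 18, 17 and 16 passed adjusted over the list alone. The mitotic cyclin gene CLB2 (YPR119W) had amplitudes of 1.09, 0.98 and 0.86, and CLB1 had 0.97, 1.10 and 1.12. SWI5, for a transcription factor of late mitosis, had 1.39, 1.16 and 1.21, and the polo kinase gene CDC5 had 1.13, 1.12 and 0.80. CDC20, for an activator of the anaphase-promoting complex, had 1.40, 1.04 and 0.73. Fisher exact adjusted p were 2.01e-09, 2.65e-12 and 2.22e-15.

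Core genes of the exit from mitosis and early G1 were also periodic. ASH1, for a repressor in daughter cells, had amplitudes of 1.74, 1.65 and 1.08. EGT2, for a cell wall protein of cell separation, had 1.76, 1.75 and 1.50. SIC1, for an inhibitor of the kinase, had 1.00, 0.78 and 0.53, and PCL9 had 1.50, 1.01 and 1.11. CTS1, for the chitinase of cell separation, had 1.33 and 1.59 and was not tested in culture E. The licensing list, which holds MCM genes and CDC6 but also CLN3, SWI4 and FAR1, was periodic for 7 of 9, 4 of 8 and 2 of 10 members, and 8, 5 and 5 adjusted over the list alone (Fisher exact adjusted p = 0.0036, 0.0344 and 0.196). Among them the cyclin gene CLN3 had amplitudes of 0.61, 0.86 and 0.65. CDC6 had adjusted p of 0.0834, 0.0505 and 0.231, POL1 had 0.296, 0.343 and 0.825, and MCM2 and MCM3 passed in no course tested. SWI4 had an amplitude of 0.97 after alpha factor and 0.29 in culture E at an adjusted p of 0.1. Of the core list, 23 of 26, 22 of 26 and 17 of 26 members were periodic, and 24, 23 and 23 adjusted over the list alone.

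**Figure D1:**
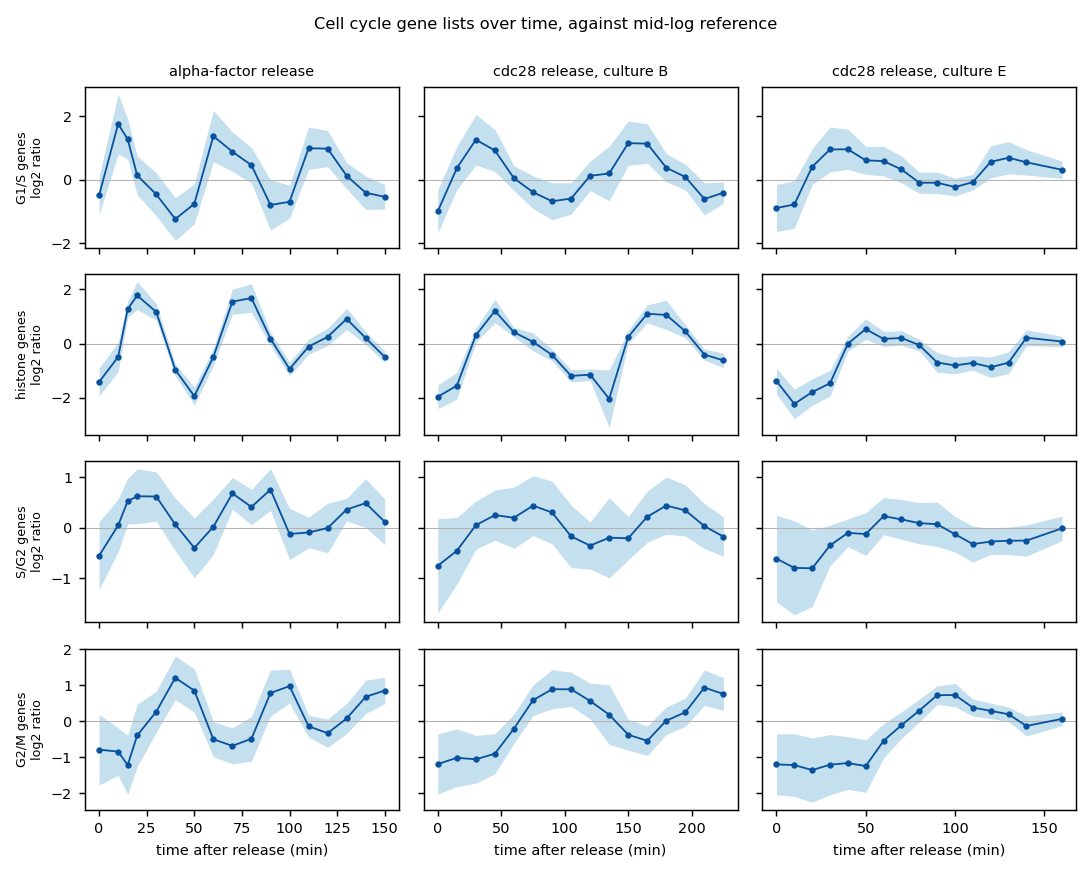
Mean log2 ratio of synchronized over mid-log cells (vertical axis) against time after release in min (horizontal axis) for the G1/S, histone, S/G2 and G2/M lists in the 3 courses; lines are means over list members and bands are 1 SD over members. The G1/S wave peaks at 13.0 min after alpha factor and at 34.3 and 41.6 min in cdc28 cultures B and E in the fitted curves.

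Outside the cell cycle lists, genes for sulfur assimilation were periodic after alpha factor for 9 of 12 members, at a mean peak of 40.8 ± 2.43 min (SD, n = 9 genes; Fisher exact adjusted p = 0.00127). Adjusted over the list alone, 9 passed. In culture B limma called 0 of 11, with 2 at an unadjusted p under 0.05 and 2 adjusted over the list alone, and in culture E it called 2 of 11, with 3 adjusted over the list alone. This difference between courses was not tested. Ribosomal protein genes were rare among periodic genes, with 9 of 126 after alpha factor (2 adjusted over the list alone) and 0 of 119 in each cdc28 culture, where 1 and 23 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone. Their Fisher exact adjusted p were 1.88e-07, 6.45e-08 and 0.00506.

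Heat shock chaperones were periodic for 0 of 22 members in each course in limma and also adjusted over the list alone, with 0, 2 and 5 at an unadjusted p under 0.05 and Fisher exact adjusted p of 0.00421, 0.102 and 0.761. Pheromone response genes were periodic for 7 of 19, 8 of 24 and 4 of 23 members, and 7, 10 and 7 adjusted over the list alone (Fisher exact adjusted p = 0.371, 0.0325 and 0.0793). Phosphate genes were periodic for 5 of 12, 5 of 12 and 3 of 12, and 5, 5 and 7 adjusted over the list alone (0.371, 0.0344 and 0.0629). Ribosome biogenesis genes gave 8 of 22, 0 of 20 and 0 of 22, and 13, 0 and 0 adjusted over the list alone, with 15, 4 and 1 at an unadjusted p under 0.05. General stress genes gave 5 of 11, 2 of 15 and 1 of 15, and 7, 3 and 2 adjusted over the list alone. Respiration genes gave 4 of 14, 0 of 14 and 0 of 15, and 4, 0 and 0 adjusted over the list alone, with 5, 1 and 1 at an unadjusted p under 0.05. Amino acid genes gave 4 of 10, 0 of 10 and 1 of 11, and 5, 0 and 1 adjusted over the list alone, with 5, 2 and 2 at an unadjusted p under 0.05. Meiosis markers gave 2 of 4, 0 of 6 and 0 of 6, with 2, 1 and 2 at an unadjusted p under 0.05, and alpha-cell markers gave 0 of 1, 0 of 4 and 0 of 4, with 0, 1 and 1.

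The next question was whether the same genes oscillate, in the same order, after both kinds of arrest. In all 3 courses 212 of 4927 genes were periodic, against 11.6 if the calls were independent. The count was 362 with quantile normalization, 132 with values on every array, 74 without a time trend and 65 with periods 10% shorter. Of these, 204 had a symbol, and 143 of the named ones stood in no list. The largest amplitudes outside the lists belonged to YGP1 (1.41, 2.30 and 1.94 after alpha factor and in cultures B and E), the cell wall gene SVS1 (1.72, 1.78 and 1.37) and the acetaldehyde dehydrogenase gene ALD6 (0.89, 2.34 and 1.68). CSI2, PRY2, TOS6, AXL2, MRH1, PST1 and MNN1 completed the 10. The mean level of YGP1 in the cdc28 cultures was 1.58 at 0 min, -2.63 at 30 min and 0.70 at 120 min. That of ALD6 was 0.73, -3.93 and -0.004. How much of the cdc28 amplitudes of YGP1 and ALD6 came from this fall after release, rather than from a cycle, was not tested. Among the genes periodic in all 3 courses the median ratio of the amplitude to that after alpha factor was 0.914 in culture B and 0.647 in culture E. The amplitude was lower than after alpha factor for 64.6% of genes in culture B and 91.5% in culture E. Pairs of courses shared 564 periodic genes for alpha factor and B (expected 194), 273 for alpha factor and E (80.7), and 235 for B and E (44.5). Without the 40 min array of culture E the count for all 3 courses was 136.

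Genes peaked in a similar order. After removal of the mean offset, peak phases differed by a median of 3.27% of the period between alpha factor and culture B, 3.41% between alpha factor and culture E, and 2.65% between B and E. The lowest of 1000 random pairings gave 19.8%, 18.4% and 16.6%, so the permutation p was 0.001 for each pair, the smallest possible. Of the 564 genes of the first pair, 516 had phases within 10% of the period of each other after removal of the mean offset. Culture E peaked 10.96% of a period later than culture B on average, and 1.34% later when both were fitted at 124 min. In that fit the median phase difference was 5.44% between alpha factor and E and 3.64% between B and E, above the values at the period of E. Phases are compared across genes, which are not independent replicates.

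**Figure D2:**
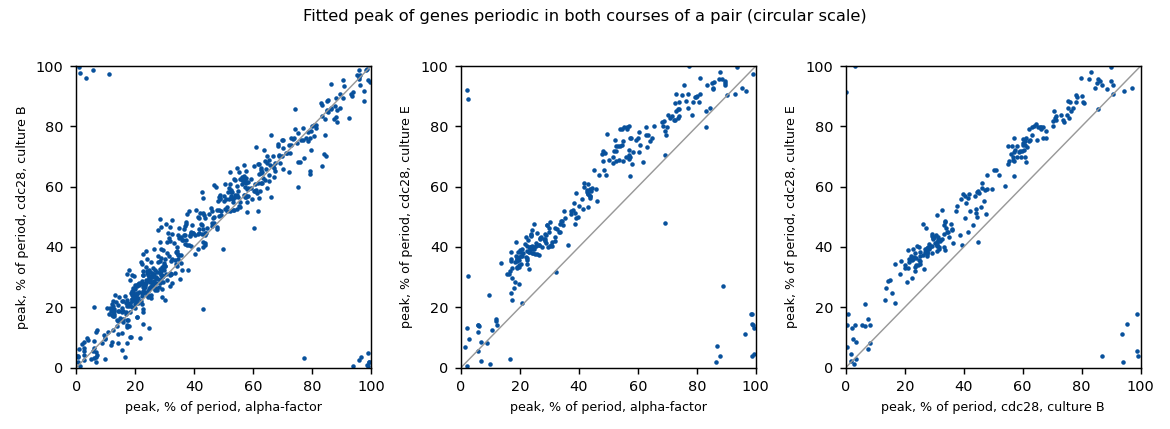
Fitted peak phase in percent of the period in 1 course (horizontal axis) against that in another (vertical axis), for the 3 pairs of courses; each dot is a gene periodic in both, and the grey line marks equal phase. The median distance after removal of the offset is 3.27%, 3.41% and 2.65% for 564, 273 and 235 genes.

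The arrests themselves were compared at 0 min. The 4 largest differences with higher levels after alpha factor were in mating genes. PRM1 (YNL279W), for a membrane protein of cell fusion, was higher by 4.90 ± 0.43 (SE), at 4.81 after alpha factor against -0.09 ± 0.35 (SD, n = 2) in the cdc28 cultures (adjusted p = 0.00126). FIG2, a mating adhesin gene, was higher by 4.84, at 4.88 against 0.04 ± 0.53 (n = 2), and AGA1 by 4.78, at 5.37 against 0.59 ± 1.24 (n = 2). The small heat shock gene HSP12 (YFL014W) was lower by the largest amount, with a difference of -5.47 ± 0.61, at 0.59 against 6.06 ± 0.45 (n = 2; adjusted p = 0.00329). In limma 204 of 5586 genes passed, 137 higher and 67 lower after alpha factor, each at least 2-fold. The alpha-factor side of each arrest difference is 1 array, which is assumed to vary like the cdc28 pairs. At 0 min the name of this array ended in the letter B and those of both cdc28 arrays in T. The array letter and the arrest therefore cannot be told apart at 0 min. Strain, temperature and culture also differ between the arrests and cannot be told apart from them at any time.

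Of 22 pheromone response genes tested, 10 were higher and 0 lower, and 12 were higher adjusted over the list alone. The mean difference of the list was 1.98 ± 1.83 (SD over 22 genes). Its camera adjusted p was 1.59e-06, and adjusted p = 0.668 with an estimated correlation. Further mating genes among the largest were PRM2 (4.63) and FIG1 (4.42, where culture B alone gave a cdc28 value at 0 min). Outside the list, CHS1 for a chitin synthase was higher by 4.05, at 2.61 against -1.44 ± 0.54 (n = 2), CMK2 for a calmodulin-dependent kinase by 3.95, and the vacuolar protease gene PRB1 by 4.30. YJL107C was higher by 3.96.

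Stress genes moved in both directions between the arrests. Of 22 heat shock chaperones 4 were higher after alpha factor and 1 lower, and 7 and 2 adjusted over the list alone. HSP42 was higher by 3.29, at 3.48 against 0.19 ± 0.49 (n = 2), and BTN2 by 3.32, while HSP12 is the member that was lower. The mean was 0.60 (camera adjusted p = 0.0311, and adjusted p = 0.668 with an estimated correlation). Of 14 general stress genes TPS2, for an enzyme of trehalose synthesis, was higher by 4.46, at 3.31 against -1.15 ± 0.02 (n = 2), and 6 were higher and 1 lower adjusted over the list alone. The list mean was 1.05 (camera adjusted p = 0.0311, and 0.668 as adjusted p with an estimated correlation). GLK1, for glucokinase, had a difference of 2.40 at an adjusted p of 0.0666, and 0.0222 with the cultures as blocks.

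Phosphate genes were lower after alpha factor for 2 of 12 members, and for 2 adjusted over the list alone. These were SPL2 at -1.97 (adjusted p = 0.0387) and VTC1, for a subunit of the polyphosphate polymerase, at -1.59 (0.042). PHM6, a gene regulated by phosphate outside the list, was lower at -3.52, with -2.84 against 0.68 ± 0.10 (n = 2). The list mean was -0.93 (camera adjusted p = 0.0185, and adjusted p = 0.668 with an estimated correlation). For ribosome biogenesis limma called 0 of 20 members over all genes, with 9 lower at an unadjusted p under 0.05, 7 lower adjusted over the list alone and 7 lower with the cultures as blocks. The list mean was -0.91 (camera adjusted p = 0.000283, and adjusted p = 0.668 with an estimated correlation). The helicase gene DBP2 had -2.16 at an adjusted p of 0.078, and 0.0322 with the cultures as blocks, and NSR1 had -2.13 at 0.115, and 0.0195 in blocks. Respiration genes had a mean of 0.80 (camera adjusted p = 0.0451, and 0.668 as adjusted p with an estimated correlation), and 0 of 14 passed, with 3 higher at an unadjusted p under 0.05 and 1 adjusted over the list alone. The citrate synthase gene CIT1 had 2.01 at an adjusted p of 0.0563, and 0.0311 with the cultures as blocks. Others among the 10 lowest were GFD2 (-3.58), LOH1 (-3.34), YOR338W (-3.08), YGR079W (-2.99), REE1 (-2.97), TRM11 (-2.77), YHR054C (-2.77) and PRM7 (-2.62).

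Ribosomal protein genes had a mean of -0.35 (camera adjusted p = 0.00605, and adjusted p = 0.874 with an estimated correlation), which turned to 0.11 with the array letter as a covariate. limma called 0 of their 120 members, with 1 higher and 2 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. In the lists that follow 0 members passed over all genes. Those at an unadjusted p under 0.05 were 2 higher of 31 G1/S genes (mean 0.45, camera adjusted p = 0.0533), 3 higher and 1 lower of 27 core genes, 1 higher of 9 histones, and 2 higher and 1 lower of 10 S/G2 genes. They were 1 higher of 18 G2/M genes (mean 0.37, camera adjusted p = 0.118), 1 higher of 9 on the licensing list, 2 higher of 11 sulfur genes and 1 higher of 10 amino acid genes. They were 1 higher and 2 lower of 4 alpha-cell markers, and 1 higher and 1 lower of 6 meiosis markers. Adjusted over the list alone, 1 and 2 alpha-cell markers and 1 and 1 meiosis markers passed, and 0 members of the other lists in this paragraph. Among alpha-cell markers MF(ALPHA)1 had -1.87 at an adjusted p of 0.107, and 0.0205 with the cultures as blocks.

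With the cultures as blocks 777 genes passed, 449 higher and 328 lower, with all 204 of the first fit among them, and without the 0 min array of culture E 111 passed. The fit with blocks takes the shift between cultures B and E as constant over time. Their difference at 0 min correlated only between -0.075 and 0.006 with that at later times. The p from the blocks may therefore be too small at 0 min and in every change from 0 min. The course as a random block gave 248, and GLK1, DBP2, NSR1, CIT1 and MF(ALPHA)1, which passed with the cultures as blocks, did not pass there. Quantile normalization left 14 genes, 8 higher (57.1% against 67.2%), and gave PRM1 a difference of 2.93 at an adjusted p of 0.0511, AGA1 2.68 at 0.0831 and HSP12 -3.88 at 0.0841. Of the 10 largest differences each way, FIG2, TPS2, CHS1, GFD2, PHM6 and YGR079W passed under it, and the remaining 14 had adjusted p of 0.0511 to 0.198. BTN2, HSP42, SPL2 and VTC1, named as members of their lists, did not pass under it either. Without the 0 min array of culture B or E, YOR338W, YHR054C, PRM7, BTN2, HSP42, SPL2 and VTC1 had adjusted p of 0.0559 to 0.108 in a fit that ended their call. With the arrays at 10 and 15 min in an early window, FIG2 had 1.52 at 0.183 and AGA1 1.10 at 0.394. The 0 min array of culture E correlated with its 10 min array at an r of 0.389 across genes.

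**Figure D3:**
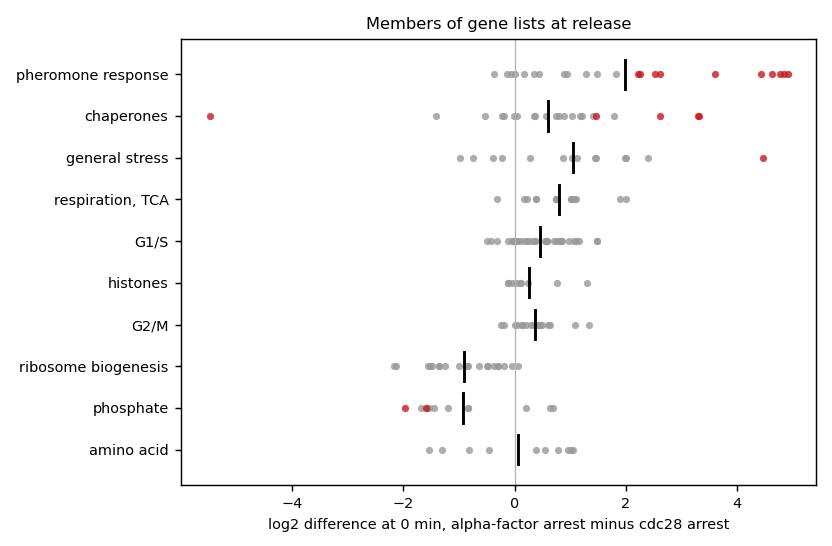
Difference in log2 ratio at 0 min, alpha factor minus cdc28 (horizontal axis), for the members of 10 gene lists; each dot is a gene, red where its adjusted p is under 0.05, and the black bar is the mean of the list. Pheromone response genes average 1.98 and ribosome biogenesis genes -0.91.

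Whether these differences were still there late was asked at 120 min. Here too strain, arrest, temperature and culture cannot be told apart. HSP82 (YPL240C), for the Hsp90 chaperone, was higher in the alpha-factor course by 3.06 ± 0.32 (SE), at 1.65 against -1.41 ± 0.25 (SD, n = 2; adjusted p = 0.0114). YIL082W-A, a retrotransposon gene, was higher by 2.78, with 2.78 in the alpha-factor course (adjusted p = 0.0114). These 2 of 5584 genes passed in limma, and 309 had an unadjusted p under 0.05. Chaperones as a list were higher by a mean of 1.67 (camera adjusted p = 5.38e-22, and adjusted p = 0.01 with an estimated correlation), against 0.60 at 0 min. HSP82 alone was past the threshold over all genes, and 15 of 22 members were higher adjusted over the list alone. Leaving out the 120 min array of culture B or of culture E left 0 genes in limma, with 179 and 306 at an unadjusted p under 0.05, and quantile normalization gave 31 genes, 24 higher (77.4%).

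The lists that follow had 0 members past the threshold at 120 min over all genes, while several shifted as groups. With periods of 53, 124 and 106 min, the courses stood at different points of the cycle by then. Shifts of the cell cycle lists therefore cannot be told apart from cycle position. General stress, ribosome biogenesis and pheromone response genes also held periodic members after alpha factor, with 5 of 11, 8 of 22 and 7 of 19. The same limit holds for their shifts. General stress genes were higher by a mean of 1.36, with 6 of 14 adjusted over the list alone and 7 at an unadjusted p under 0.05 (camera adjusted p = 7e-08, and adjusted p = 0.214 with an estimated correlation). Histones had 1.25 (1.75e-06, and adjusted p = 0.291 with an estimated correlation), and 2 of 9 an unadjusted p under 0.05. G1/S genes had 0.65 (1.14e-08, and 0.291), with 6 of 32 at an unadjusted p under 0.05. The G2/M cluster was lower at -0.72, with 5 of 18 adjusted over the list alone and 7 at an unadjusted p under 0.05 (1.02e-09, and adjusted p = 0.0694 with an estimated correlation). Ribosome biogenesis genes had -0.85 (8.5e-09, and 0.291), with 5 of 20 at an unadjusted p under 0.05. Pheromone response genes had a mean of -0.22 (camera adjusted p = 0.126), with 2 of 22 lower at an unadjusted p under 0.05.

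The change of the arrest difference from 0 to 120 min was tested directly. Several mating genes lost their excess: PRM1 changed by -4.97 (adjusted p = 0.028), FIG2 by -4.88 (0.028), FIG1 by -4.65 (0.0389, with 1 cdc28 value at 0 min) and PRM2 by -4.59 (0.0389). CHS1 changed by -3.99 (0.0389), and HSP12 changed by 6.17 (0.0389), with a level in the cdc28 cultures that went from 6.06 ± 0.45 to -0.35 ± 0.84 (SD, n = 2). In limma 11 of 5579 genes passed, 1 up and 10 down, and 24 passed with the cultures as blocks. Of 22 pheromone response genes 4 fell, and 13 adjusted over the list alone (mean -2.20; camera adjusted p = 1.81e-12, and adjusted p = 0.0904 with an estimated correlation). The G2/M cluster had a mean of -1.09 (1.78e-08, and 0.0904 as adjusted p with an estimated correlation) and 0 of 18 members past the threshold, with 6 lower at an unadjusted p under 0.05. Because the courses stood at different points of the cycle at 120 min, this shift cannot be told apart from cycle position. Chaperones had a mean of 1.07 (7.24e-06, and 0.0904 as adjusted p with an estimated correlation), with HSP12 past the threshold, 2 of 22 higher adjusted over the list alone and 7 higher at an unadjusted p under 0.05. Quantile normalization gave 0 genes in limma, with 315 at an unadjusted p under 0.05. Leaving out an array gave 0 (culture E at 0 min, 399 at an unadjusted p under 0.05), 0 (culture E at 120 min, 287), 2 (culture B at 0 min) or 6 (culture B at 120 min).

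Genes that change after the return to permissive temperature were sought in the cdc28 cultures against 0 min. By 30 min the G1/S wave had come on and stress genes had fallen. CLB6 (YGR109C), an S-phase cyclin gene, rose by 4.11 ± 0.40 (SE), from -0.94 ± 0.04 to 3.17 ± 0.06 (SD, n = 2; adjusted p = 0.0024). DDR2 (YOL052C-A), a stress gene, fell by 4.72, from 2.48 ± 1.18 to -2.24 ± 0.18 (n = 2; adjusted p = 0.00284). In limma 296 of 5568 genes passed, 135 higher and 161 lower, of which 291 changed at least 2-fold.

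Of 32 G1/S genes 24 rose and 0 fell, and 27 rose adjusted over the list alone, with a mean change of 2.05 ± 1.21 (SD over 32 genes). MCD1, for a cohesin subunit, rose by 4.10, from -2.48 ± 0.40 to 1.62 ± 0.95 (n = 2). RNR1 rose by 4.05, from -2.39 ± 0.50 to 1.67 ± 0.04 (n = 2), CLN1 by 3.44 and POL30, for the sliding clamp of DNA replication, by 3.28. The repressor gene YOX1 rose by 3.88 and TOS4 by 3.59. The camera adjusted p was 3.76e-20, and adjusted p = 0.2 with an estimated correlation. Outside the lists SVS1 rose by 4.66, from -2.62 ± 0.78 to 2.04 ± 0.85 (n = 2), CSI2 by 3.71 and TOS6 by 3.61. Of 27 core genes 6 rose, and 7 rose and 2 fell adjusted over the list alone (mean 0.70; camera adjusted p = 0.0135, and adjusted p = 0.349 with an estimated correlation).

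Of 14 general stress genes 10 fell and 0 rose, and 14 fell adjusted over the list alone, with a mean of -2.66 (camera adjusted p = 9.28e-09, and adjusted p = 0.2 with an estimated correlation). The nicotinamidase gene PNC1 changed by -4.17 and MSC1 by -3.80. Heat shock chaperones fell for 11 of 22 members, and for 14 adjusted over the list alone, with a mean of -1.45 (6.86e-11, and adjusted p = 0.0547 with an estimated correlation). HSP104, for the disaggregase, changed by -3.12, from -0.12 ± 0.09 to -3.24 ± 0.48 (n = 2), HSP42 by -2.59 and HSP26 by -2.37. Outside these lists ALD6 changed by -4.66, GPD1 for glycerol phosphate dehydrogenase by -4.25, YGP1 by -4.21 and RTC3 by -3.95. GAD1, for glutamate decarboxylase, changed by -3.76, GPM2 by -3.70 and NCE102 by -3.64. Respiration genes fell for 1 of 14 members, 4 adjusted over the list alone and 7 with the cultures as blocks, with CIT1 at -2.80 and a median of -1.08 (camera adjusted p = 0.00128, and adjusted p = 0.302 with an estimated correlation).

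Of 9 histones HHO1 rose at 30 min, by 1.94, and 3 rose adjusted over the list alone (mean 1.09; camera adjusted p = 0.00241, and adjusted p = 0.526 with an estimated correlation). Of 10 S/G2 genes WHI5 rose by 1.49 and STU2 by 1.27, and 6 rose and 1 fell adjusted over the list alone (mean 0.60, camera adjusted p = 0.078). Ribosome biogenesis genes rose for 2 of 19 members and 8 adjusted over the list alone, with the fibrillarin gene NOP1 at 1.52 (mean 0.86; 2.19e-05, and adjusted p = 0.389 with an estimated correlation). Phosphate genes rose for 1 of 12 members, and for 1 adjusted over the list alone (mean 1.09; 0.00372, and adjusted p = 0.389 with an estimated correlation), and PHO11 had 2.30 at an adjusted p of 0.124. Ribosomal protein genes rose for 1 of 120 and for 0 adjusted over the list alone (mean 0.40; 0.000108, and adjusted p = 0.676 with an estimated correlation).

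Amino acid biosynthesis genes had a mean change of 1.08 at 30 min, and 0 of 10 passed in limma over all genes, with 6 higher at an unadjusted p under 0.05 and 4 adjusted over the list alone. Their camera adjusted p was 0.0254, and adjusted p = 0.537 with an estimated correlation. ARG1 had 2.64 at an adjusted p of 0.0944 and HIS4 had 2.53 at 0.138. Of 4 alpha-cell markers MF(ALPHA)1 fell by 2.46, alone also when adjusted over the list alone. In limma 0 of 18 G2/M genes, 22 pheromone response genes, 11 sulfur genes, 9 members of the licensing list and 6 meiosis markers passed. Those at an unadjusted p under 0.05 were 0 G2/M genes, 2 lower pheromone response genes, 0 sulfur genes, 3 higher and 1 lower on the licensing list and 2 lower meiosis markers.

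With the cultures as blocks 610 genes passed at 30 min, including all 296, and quantile normalization gave 91, of which 31 were higher (34.1% against 45.6%). The shift between cultures B and E at 0 min was not that of later times. The p from the blocks may therefore be too small here and in the later changes against 0 min. Without 1 array the count was 79 (culture E at 0 min), 467 (culture B at 0 min), 108 (culture B at 30 min) or 125 (culture E at 30 min). Leaving out 1 of these ended the calls of RNR1, CSI2, TOS6, GPD1, HHO1, WHI5, STU2, HSP42, HSP26, NOP1, CIT1 and MF(ALPHA)1, at adjusted p of 0.055 to 0.206. Quantile normalization ended those of TOS6, HHO1, WHI5, STU2, HSP42, HSP26, NOP1 and MF(ALPHA)1, at 0.0516 to 0.153.

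At 60 min the histone wave followed, with 3 of 9 histone genes higher and 9 adjusted over the list alone, at a mean change of 1.96 (camera adjusted p = 8.39e-07, and adjusted p = 0.266 with an estimated correlation). G1/S genes were up for 8 of 32 members, 21 adjusted over the list alone and 17 with the cultures as blocks, with a mean of 1.26 (1.86e-11, and adjusted p = 0.25 with an estimated correlation). Chaperones were down for 11 of 22 members, and 13 adjusted over the list alone, at a mean of -1.59 (1.86e-11, and adjusted p = 0.0487 with an estimated correlation). General stress genes were down for 8 of 14, and 11 adjusted over the list alone. The largest rises were in SVS1 (4.27), SIM1 (3.71), CIS3 (3.18), MCD1 (2.97) and TOS6 (2.96), of which SVS1, SIM1 and CIS3 encode cell wall proteins. The largest falls were in ALD6 (-4.93), YGP1 (-4.76), DDR2 (-4.70), HSP12 (-4.62) and HOR7 (-4.11). In limma 248 of 5591 genes passed, 110 higher and 138 lower. Blocks gave 580 with all 248 among them, and quantile normalization gave 131 and put HSP12 at -2.61 with an adjusted p of 0.0846 and TOS6 at 2.83 with 0.103. Without 1 array the count was 30 (culture E at 60 min), 56 (culture B at 60 min), 65 (culture E at 0 min) or 311 (culture B at 0 min). Leaving out the 60 min array of culture E put SVS1, SIM1, CIS3, MCD1 and TOS6 at adjusted p of 0.0553 to 0.271, and TOS6 and SIM1 also lost their call without that of culture E at 0 min (0.154 and 0.0578). TOS6 had 0.122 without culture B at 0 min and 0.104 without it at 60 min. Phosphate genes had a mean of -0.10 and a median of 0.07 (camera adjusted p = 0.681).

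By 90 min the mitotic genes had risen. SWI5 rose by 4.03 (adjusted p = 0.000718), CLB1 by 3.24 and CLB2 by 3.02, from -1.83 ± 0.22 to 1.19 ± 0.09 (SD, n = 2). Of 18 G2/M genes 13 rose, and 16 adjusted over the list alone, with a mean of 1.95 (camera adjusted p = 1.3e-19, and adjusted p = 0.0206 with an estimated correlation). SIM1 rose by 3.19, with an adjusted p of 0.0857 without the 0 min array of culture E, and CIS3 rose by 3.13. HSP12 changed by -6.53, DDR2 by -4.51, HOR7 by -3.93, SPI1 by -3.91 and NCA3 by -3.62. Chaperones were down for 10 of 22 members, and 13 adjusted over the list alone (mean -1.57; 2.67e-12, and adjusted p = 0.0206 with an estimated correlation). In limma 176 genes passed, 76 higher and 100 lower, and 465 in blocks with all 176 among them. Without 1 array the count was 67 (culture B at 90 min), 85 (culture E at 0 min), 97 (culture E at 90 min) or 366 (culture B at 0 min).

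At 120 min EGT2 rose by 3.34, from -2.47 ± 0.80 to 0.87 ± 0.18 (SD, n = 2). SWI5 was still up by 3.43, at 0.55 ± 0.39 (n = 2), and 10 of 18 G2/M genes were up, 15 adjusted over the list alone (mean 1.59; 1.64e-16, and adjusted p = 0.0257 with an estimated correlation). Of 27 core genes 11 rose, 16 adjusted over the list alone (mean 1.34; 4.96e-11, and adjusted p = 0.0291 with an estimated correlation). PHO81, for a phosphate regulator, rose by 3.39, the glutamate dehydrogenase gene GDH1 by 3.16, and SVS1 by 3.22. Without the 0 min array of culture E, SVS1, GDH1 and PRM7 had adjusted p of 0.145, 0.133 and 0.0559. Without its 120 min array SVS1 had 0.104 and GDH1 0.0768, and without that of culture B GDH1 had 0.0639. HSP12 changed by -6.41, DDR2 by -4.15, PRM7 by -3.58, YOR338W by -3.49 and NCA3 by -3.41, and chaperones were down for 7 of 22, 12 adjusted over the list alone (mean -1.45; 2.28e-11, and adjusted p = 0.0257 with an estimated correlation). In limma 136 genes passed, 65 higher and 71 lower, and 416 in blocks with all 136 among them. Without 1 array the count was 31 (culture E at 0 min), 44 (culture E at 120 min), 48 (culture B at 120 min) or 298 (culture B at 0 min).

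**Figure D4:**
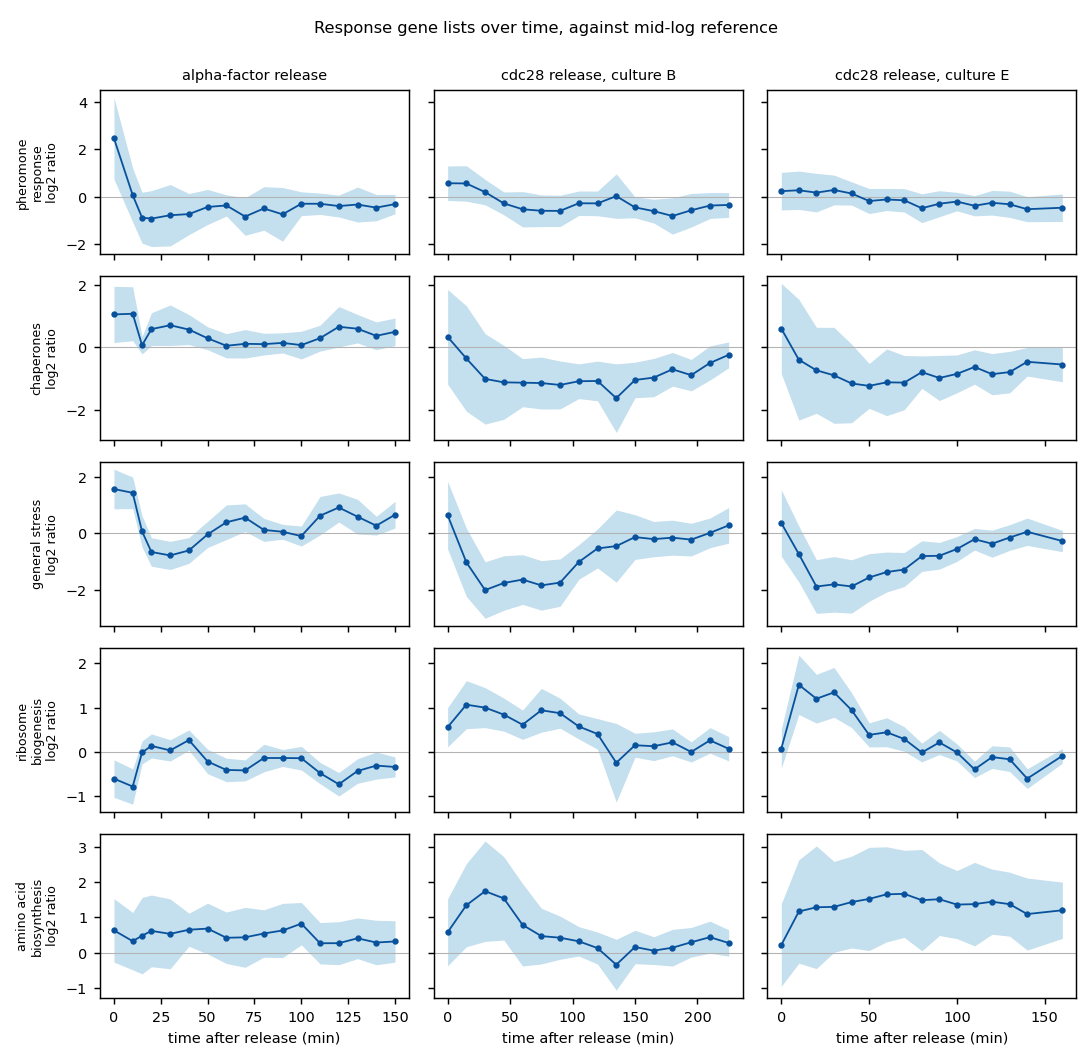
Mean log2 ratio of synchronized over mid-log cells (vertical axis) against time after release in min (horizontal axis) for the pheromone response, chaperone, general stress, ribosome biogenesis and amino acid lists in the 3 courses; lines are means over list members and bands are 1 SD over members. Pheromone response genes average 2.47 at 0 min and -0.77 at 30 min after alpha factor, and amino acid genes average 0.13 in culture B and 1.44 in culture E at 120 min.

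The cdc28 cultures were compared with each other at each shared time. Across genes, which are not independent replicates, cultures B and E correlated with r of 0.652 at 0 min, 0.699 at 30 min, 0.639 at 60 min, 0.415 at 90 min and 0.213 at 120 min. Spearman's rho was 0.607, 0.645, 0.541, 0.270 and 0.0609. The SD of their difference ranged from 0.456 at 60 min to 0.616 at 0 min, and was 0.599 at 90 min and 0.578 at 120 min. The deviation of B from E correlated between 0.540 and 0.873 among the later times, and between -0.075 and 0.006 with 0 min. At 0 min the names of both arrays ended in the letter T. At the later shared times the array of culture B ended in T and that of culture E in B. The array letter and the culture therefore cannot be told apart at those times.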

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

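No test of the 6 genes below was chosen after its result was seen. They drew attention because the difference between the alpha-factor and cdc28 courses at 120 min differed from that at 0 min in a limma test of the change itself. The change was -4.97 for PRM1, -4.88 for FIG2, -4.65 for FIG1, -4.59 for PRM2, -3.99 for CHS1 and 6.17 for HSP12, with adjusted p of 0.028 for PRM1 and FIG2 and 0.0389 for the others. FIG1 had 1 cdc28 value at 0 min, from culture B, so its change rests on single arrays at that time. The alpha-factor level of PRM1 was 4.81 at 0 min and -0.22 at 120 min, and the cdc28 mean was -0.09 and -0.15. For CHS1 both sides moved: the alpha-factor level was 2.61 at 0 min and 0.86 at 120 min, and the cdc28 mean -1.44 and 0.79. Quantile normalization left 0 genes past the threshold in limma, with 315 at an unadjusted p under 0.05. Without the 0 min or the 120 min array of culture E, 0 genes passed, with 399 and 287 at an unadjusted p under 0.05. Without the 0 min array of culture B 2 passed, and without its 120 min array 6 passed.

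The counts of periodic genes were set against 100 shuffles of the array order in each course, with the period set again in each. After alpha factor 0 shuffles gave as many as the 1404 genes of the real order, and the highest gave 338. In culture B 0 shuffles gave as many as 796, and the highest gave 131, so an arbitrary order is excluded for these courses. In culture E 5 of 100 gave as many as the real 328, so this count alone does not exclude an arbitrary order there. The peak phases of culture E lay closer to those of the other courses than in random pairings of genes. That closeness was not set against shuffles of the arrays. The highest shuffle of culture E gave 1402, several times the real count, and 92 of the 100 gave 0 genes at an adjusted p under 0.05. What gave the high count was not tested. With periods in steps of 4 min for the shuffles, 4 of 100 gave as many as the real order. The residuals of arrays on the same slide correlated at 0.628 in culture E in the limma fit, against 0.130 in culture B and 0.027 after alpha factor, and the slide as a random block gave 387 periodic genes in culture E. Whether the slides account for the high shuffle was not tested.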

How the results depend on the processing

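Culture E at the period of B and named genes only were alternatives chosen after the data were seen. Named genes reversed in 0 cases: 2064 contrast values kept their side of the threshold, 71 newly passed and 119 no longer passed, and for amplitudes the numbers were 1497, 27 and 74. For list shifts they were 857, 18 and 75, and 2 reversed. The reversed ones were ribosomal proteins with the array letter as a covariate, at 0.11 for 0 min and 0.0637 for 120 min.

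Periodic counts for culture E were 572 with quantile normalization, 95 without a time trend, 568 with a quadratic trend, 211 with a period 10% shorter, 526 without the arrays up to 20 min and 532 at the period of B. Counts for all 3 courses were 362 with quantile normalization, 132 with values on every array, 74 without a trend and 65 with the shorter periods. Culture B gave 523 with values on every array and 488 with the shorter period, and alpha factor gave 215 with the shorter period. An amplitude of at least 0.5 left 482, 366, 160 and, in all 3 courses, 123 genes, since fewer genes can pass.

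For the contrasts, quantile normalization gave 14 genes at 0 min, 31 at 120 min and 0 for their change (limma, 315 at an unadjusted p under 0.05), and 91 and 131 for cdc28 cells at 30 and 60 min. The cultures as blocks, which pair the arrays of B and E over time, gave 777 at 0 min, 24 for the change of the arrest difference, and 610, 580, 465 and 416 for cdc28 cells at 30 to 120 min. Blocks assume a constant shift between B and E, and the shift of the later times did not extend to 0 min. Each of these block counts uses the 0 min arrays, so the p behind it may be too small. The course as a random block gave 248 at 0 min, 20 for that change and 603, 556, 436 and 377. The array letter gave 401, 6 and 44 for the arrest contrasts and 645, 532, 487 and 350 for cdc28 cells. In these fits the letter rests only on the cdc28 pairs at 30 to 120 min, where it equals the culture. An early window, with the arrays at 0, 10 and 15 min as 1 early group, held 7 arrays and gave 1481 genes, with 168 of the 204 among them. It pools times and counts successive arrays of the same culture as replicates, so it is not a result at 0 min. The slide as a random block was not run for the contrasts, as their 15 arrays lie on different slides. With an estimated correlation camera called 7 list shifts against 66. Spearman's rho between B and E was 0.607, 0.645, 0.541, 0.270 and 0.0609. Where the construction does not show it, the cause was not tested.

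Leaving out 1 array gave ranges of 1018 to 1523 periodic genes after alpha factor, 611 to 1031 in culture B, 196 (without 40 min) to 568 (without 160 min) in culture E and 136 (without 40 min of E) to 295 in all courses. Culture E also gave 515 without 0 min, 204 without 60 min, 202 without 70 min and 210 without 80 min. Median phase differences, as a fraction of the period, stayed at 0.0295 to 0.0363, 0.0309 to 0.0414 and 0.0225 to 0.0325. For contrasts an arm is then left with 1 array, which is assumed to vary like the other groups. The ranges were 111 (without E at 0 min) to 169 at 0 min, 0 to 0 at 120 min (179 without B and 306 without E at an unadjusted p under 0.05 in limma), and 0 to 6 for the change. They were 79 to 467 at 30 min, 30 to 311 at 60 min, 67 to 366 at 90 min and 31 to 298 at 120 min for cdc28 cells, with the lowest without E at 0 min, E at 60 min, B at 90 min and E at 0 min, and the highest without B at 0 min. The number of arrays limits these results, and signal over background was not analysed here.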

Other observations

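The tests of a wrong label and of noise on the 135 min array, both tests of the later phase of culture E, and the test of a constant shift of the amino acid list were chosen after the result was seen. Genes for amino acid biosynthesis, targets of the activator Gcn4, were high late in cdc28 culture E. Their mean log2 ratio in culture E was 0.22 at 0 min, 1.30 at 30 min, 1.65 at 60 min, 1.51 at 90 min and 1.44 at 120 min. In culture B it was 0.58, 1.74, 0.79, 0.43 and 0.13, and in the alpha-factor course 0.27 at 120 min. At 120 min ARG1, for argininosuccinate synthase, stood at 3.09 in culture E and 0.78 in culture B, and ARG3 at 2.67 and -0.18. At 120 min the ratio was higher in culture E for 11 of 11 members.

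YIL082W-A, a retrotransposon gene, stayed high through the alpha-factor course, at 2.63, 4.06, 3.39, 2.10 and 2.78 at the shared times. Its cdc28 mean at 0 min was 0.30 ± 0.16 (SD, n = 2). Phases of named genes were also compared as culture B minus alpha factor, after removal of the mean offset. The largest differences, chosen after their values were seen, were in ECM15 (-26.0% of the period), MHT1 (23.2%), TPO2 (-18.8%) and SMF2 (18.2%). FPS1 followed with -18.0%, and the purine genes ADE4 and ADE17 with -17.6% and -17.3%.

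The late amino acid pattern was weighed against shifts that are not specific to time. The mean difference E minus B at 90 and 120 min was 1.20 ± 0.84 (SD over 11 genes). At 0 and 30 min it was -29.8% of that (95% bootstrap interval over genes -78.0 to -0.026). A constant shift from the mid-log reference of a culture would not give this. The list was picked after its late values were seen, so this describes the pattern and is not an independent test. The interval leaves out variation between cultures. Quantile normalization kept 121% of the late difference and the values as deposited kept 99.1%, which argues against centring or scaling as its source. A difference between the cultures themselves may account for it and stays open, untested, with 1 culture on each side.

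The array of culture B at 135 min stood apart from its neighbours in time and held the fewest values, 4189. Its highest correlation with any other array was 0.372, with that at 120 min, below the 0.589 of the least matched of the other 48. Noise or few values would lower every correlation, so this cannot tell whether the time label was wrong or the array was swapped within the series. The SD of the 135 min array around the mean of its neighbours was 0.915 over 4802 genes that are not periodic, against 0.167 to 0.493 for the other inner arrays. Noise on this array would give this, but so would a swap or a real change, so it does not point to noise in particular. The arrays at 120 and 150 min correlated at 0.802, above the lowest of other pairs at 0.491, but a change that came and went between them would leave both alike, so that bound was wrongly set, and a short-lived change of the culture cannot be told apart from noise. Without this array culture B had 1031 periodic genes.

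Culture E peaked later in its cycle than culture B, by 10.96% of the period. Fitted at the 124 min of culture B the offset was 1.34%, as a period of culture E set too short by its shorter span would give. Culture B cut to the span of E, up to 160 min, kept a period of 125 min, which goes against the span, so whether the span accounts for the offset cannot be told from these values. Without its arrays up to 20 min culture E had a period of 107 min. The G1/S list of culture E aligned best with that of B at a lag of 7 min up to 75 min, so a later first wave may also contribute. The 95% bootstrap interval over genes was 7 to 8 min. It leaves out variation between cultures and the spacing of the arrays in time. These explanations were not separated further, and a difference between the cultures stays open.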
